A study of Mus musculus with 11 samples.

How the data were processed

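Lineage-negative, cKit-positive, Sca-1-positive (LSK) cells were sorted from mouse bone marrow on a BD FACSAria II, and total RNA of individual mice was sequenced as paired reads on an Illumina NextSeq 500, per the labels. The 11 libraries came from wild-type mice (WT, n = 4), Phf6 knockout mice (KO, n = 3) and mice labelled Phf6 R274X Tg (Tg, n = 4). The labels give the strain C57BL/6 for every library and give no age, sex or batch. The authors deposited raw read counts per gene symbol for the whole series, with no normalisation. The submitters' processing notes name FastQC, Trimmomatic, STAR and HTSeq and the genome build mm10. Their versions, the gene annotation, the strand setting and any filter are not given in the sources used here.

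The table held 55291 gene symbols, of which 24894 had a count of 0 in every library. Totals per library ran from 20990446 to 45632018 counts, so that 3 counts, the limit a count of 0 allows, corresponded to 0.0657 to 0.143 CPM (counts scaled to a common library total). This limit covers counting error only, since the reads carry no molecular identifiers. Biotypes and coordinates came from GENCODE M21 (GRCm38, the assembly of mm10), matched by symbol for 53186 symbols and for 16776 of the 17183 genes tested. Reads of near-identical copies (pseudogenes, immunoglobulin segments) could be split between genes by the counting, so single members of those families are uncertain, and so are overlapping genes.

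All 11 libraries were fitted together with edgeR 4.0.16 under R 4.3.3, with TMM factors, filterByExpr on the group and no covariate. Each contrast (KO against WT, Tg against WT, Tg against KO) was tested with edgeR's quasi-likelihood test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.272, with 8 residual and 3.43 prior degrees of freedom. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. CPM values are TMM normalised and given as mean ± SD, except those of Xist and of Y-linked genes per library, which use library totals. A total of 35 gene lists, fixed before the data were examined, were tested with limma 3.58.1 (camera, preset correlation 0.01, adjusted over the lists within a contrast). Symbols absent from the table were matched through RefSeq synonyms.

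The genes named were set by a rule: Phf6 in every library, and for each contrast the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM over the 11 libraries and no overlap between the groups, leaving out predicted gene models. Up to 4 members with the lowest p were added for each list described, and where fewer than 5 genes were called the 5 with the lowest p were named. Xist, Ddx3y, Uty, Kdm5d and Eif2s3y were read as a check of the libraries. Some genes that the rule names are not reported here. Genes outside this rule are marked as chosen after their values were seen.

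The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, no filter or a stricter filter on low counts (2 CPM in 3 libraries), fits of only the groups compared, the replicate number as a block, a surrogate variable (sva 3.50.0), a test against a 1.2-fold change, each library left out in turn, and for lists an estimated correlation and fry. A further 4 were added after the data were examined: autosomal protein-coding genes alone, the Y-linked level as a covariate, leaving out the libraries with both Xist and Y-linked reads, and robust empirical Bayes. The fit was tested on simulated data with known changes: it recovered 32.8%, 79.1% and 93.9% of genes changed 1.5-, 2- and 4-fold in a fit of 16865 genes for KO against WT, and 46.3%, 79.1% and 97.0% in a fit of 16861 genes for Tg against WT. The changed genes were drawn from those with a mean of at least 5 CPM. Counts were simulated independently for each gene with dispersions estimated from these libraries. The recovered shares therefore do not cover genes of lower level. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.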

Results

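The transcriptome of LSK cells, the bone marrow fraction that holds haematopoietic stem cells and multipotent progenitors, was measured in 4 WT, 3 KO and 4 Tg mice. Phf6 is an X-linked gene for a plant homeodomain protein of chromatin that is mutated in human leukaemias, and R274X places a stop codon in it. Libraries held a mean of 28460000 ± 4983000 counts in WT, 36480000 ± 8066000 in KO and 35800000 ± 6009000 in Tg, and 17183 genes were tested. Spearman correlations between libraries had medians of 0.979 within WT, 0.985 within KO, 0.983 within Tg, 0.979 between KO and WT, 0.972 between Tg and WT and 0.967 between Tg and KO. The first principal component held 35.1% of the variance and placed all 4 Tg libraries apart from the WT and KO libraries.

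**Figure D1:**
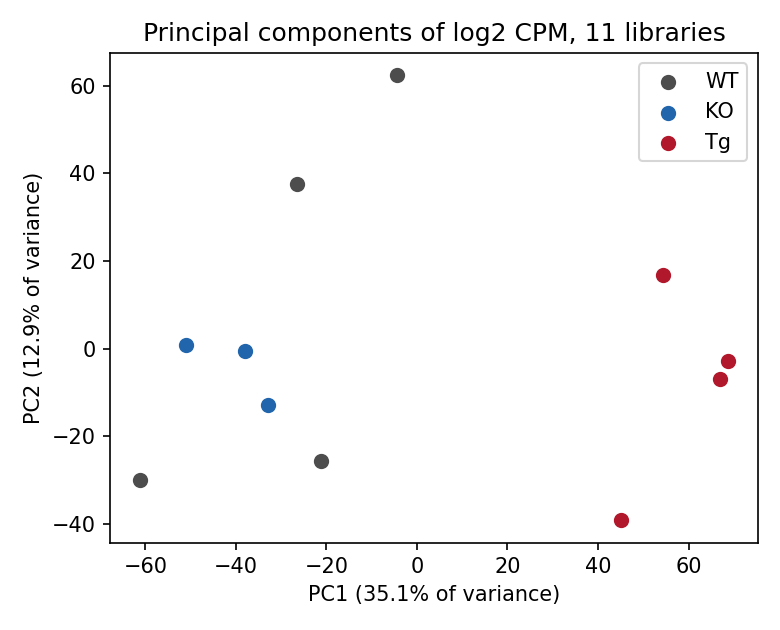
Principal components 1 and 2 of log2 CPM for the 11 libraries, 1 point per library, coloured by genotype. The 4 Tg libraries lie between 44.98 and 68.74 on the first component and the WT and KO libraries between -61.2 and -4.33.

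Phf6 itself (X chromosome, 52912266 to 52956943, plus strand, GRCm38) was read first in every library. Its level was 121.2 ± 14.2 CPM in WT (SD, n = 4), 19.4 ± 4.33 in KO (n = 3) and 220.1 ± 46.1 in Tg (n = 4). The WT libraries held 141.9, 117.1, 115.7 and 109.9 CPM, the KO libraries 23.96, 18.8 and 15.4, and the Tg libraries 182.6, 183.2, 237.0 and 277.7. Phf6 transcripts fell by 2.64 on the log2 scale in KO (SE 0.19, adjusted p = 0.000352 by edgeR's quasi-likelihood test) and rose by 0.86 in Tg against WT (SE 0.16, adjusted p = 0.0176). Without WT replicate 2 the latter call was lost (0.85, adjusted p = 0.0563). Counts per gene do not separate an endogenous from a transgenic transcript.

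**Figure D2:**
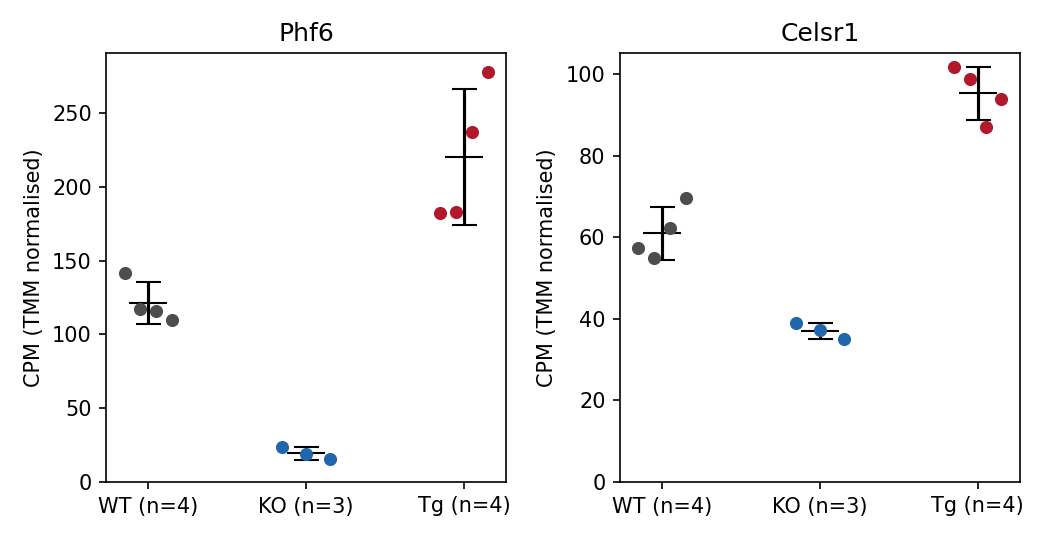
Phf6 and Celsr1 in normalised CPM per library (points), with mean and SD (bars), for WT (n = 4), KO (n = 3) and Tg (n = 4). Both genes have their lowest mean in KO, where Phf6 averages 19.4 CPM, and their highest in Tg, where it averages 220.1 CPM.

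The first comparison asked what loss of Phf6 changes in LSK cells. In KO, Celsr1, a cadherin of the planar cell polarity pathway, fell by 0.72 on the log2 scale (SE 0.093, adjusted p = 0.0323), from 61.0 ± 6.51 to 37.1 ± 2.00 CPM. Chl1, a neural cell adhesion molecule, rose by 3.46 (SE 0.39, adjusted p = 0.0162), from 0.643 ± 0.184 to 7.11 ± 3.53 CPM. Leaving out 1 library ended the call of Celsr1 for 8 of the 11 libraries (adjusted p up to 0.238, without KO replicate 3). It ended that of Chl1 for 5 (up to 0.0934, without WT replicate 4). In all, edgeR called 4 genes, 1 higher and 3 lower. Dhx58, which encodes the RIG-I-like receptor LGP2, lay at 39.4 ± 5.47 CPM in KO and 21.8 ± 3.49 in WT and did not pass (log2 fold change 0.86, SE 0.14, adjusted p = 0.148).

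Of the gene lists, interferon response genes stood out in KO: 39 of 40 lay above WT, with a median log2 fold change of 0.635. In edgeR none of the 40 passed over all genes, 16 passed adjusted over the list alone, 21 had an unadjusted p under 0.05, and DESeq2 called 6. Ifit1, an antiviral effector, had a log2 fold change of 1.89 (SE 0.42), Usp18, a brake on interferon signalling, 1.38 (SE 0.33), Xaf1 0.99 (SE 0.23) and Rtp4 0.86 (SE 0.21), each passing over the list alone and none over all genes. KO replicate 1 had the highest list mean, 5.58 on the log2 CPM scale against 4.83 and 5.10 in the other KO libraries. Without it the log2 fold change of Ifit1 was 1.09, that of Usp18 0.98 and that of Rtp4 0.59. The list was called higher by camera (adjusted p = 1.76e-26; adjusted p = 0.424 with an estimated correlation).

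In KO, macrophage genes (4 of 17 above WT, median -0.28; camera adjusted p = 0.104) and mature neutrophil genes (8 of 15, median 0.01; 0.328) were not called. Granulocyte-monocyte progenitor genes were above WT for 18 of 20 members (median 0.82; camera adjusted p = 2.8e-11; adjusted p = 0.599 with an estimated correlation), with no member passing either way in edgeR, 6 at an unadjusted p under 0.05 and 0 called by DESeq2. Csf1r, the receptor for the macrophage growth factor, had a log2 fold change of 1.22 (SE 0.34). In the monocyte and dendritic cell list (camera adjusted p = 2.35e-06; adjusted p = 0.599 with an estimated correlation), the chemokine receptors Cx3cr1 (1.40, SE 0.31) and Ccr2 (1.27, SE 0.37) and Ly86 (1.02, SE 0.31) passed adjusted over the list alone, and none of the 17 members passed over all genes in edgeR, with 4 at an unadjusted p under 0.05 and 1 called by DESeq2. The mean of the monocyte and dendritic cell list in WT replicate 2, 4.77 on the log2 CPM scale, lay above every KO library (3.699 to 4.525). Stem cell identity genes were below WT for 23 of 26 members. Their list mean in WT replicate 3, 4.513, lay below those of KO replicates 1 and 3 (4.589 and 4.592). That list was called lower (median -0.35; camera adjusted p = 2.06e-07; adjusted p = 0.599 with an estimated correlation), with Sult1a1 at -1.66 (SE 0.42) and Procr, a surface marker of stem cells, at -0.74 (SE 0.25), neither passing. In the stem cell ageing list (camera adjusted p = 9.3e-06; adjusted p = 0.599 with an estimated correlation), Gstm2 (-2.28), Sult1a1 (-1.66), Cpne8 (-1.36) and Neo1 (-1.47) passed adjusted over the list alone, and Hoxb2 (-1.67, SE 0.36) did so in the Hox list (camera adjusted p = 0.000842; adjusted p = 0.599 with an estimated correlation). In edgeR no member of these 3 lists passed over all genes; 9, 7 and 4 members had an unadjusted p under 0.05 and DESeq2 called 1, 3 and 1. Without WT replicate 1 the Hox list was not called (camera adjusted p = 0.0502). Its mean in WT replicate 3, 1.488, lay below that of KO replicate 3, 1.521. The means of the granulocyte-monocyte progenitor and stem cell ageing lists did not overlap between KO and WT.

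Camera called 6 other lists in KO. Nuclear oxidative phosphorylation genes (53 of 60 above WT, median 0.15; camera adjusted p = 1.49e-07), cytoplasmic ribosomal protein genes (68 of 78, median 0.11; 9.17e-07), class I antigen presentation (14 of 15, median 0.20; 0.00179), B cell genes (12 of 18, median 0.25; 0.0119) and ribosome biogenesis (27 of 37; 0.0343) were called higher, and megakaryocyte genes (4 of 18 above WT; 0.0476) lower. With an estimated correlation the adjusted p was 0.845 for all of these but class I antigen presentation, at 0.599. No member of these 6 lists passed either way in edgeR, 2, 6, 2, 0, 0 and 1 had an unadjusted p under 0.05 in that order, and DESeq2 called 0. The camera call was lost without WT replicate 1 for class I antigen presentation (adjusted p = 0.109) and B cells (0.0520), and without WT replicate 2 for ribosomal protein (0.126), megakaryocyte (0.5) and ribosome biogenesis (0.938) genes. It was also lost without WT replicate 3 for B cells (0.651), without WT replicate 4 (0.0615) or KO replicate 3 (0.553) for ribosome biogenesis and without KO replicate 2 for megakaryocyte genes (0.890). Across all genes edgeR found 573 above and 645 below WT at an unadjusted p under 0.05, while DESeq2 called 55 higher and 52 lower. The calls besides Phf6 were lost in several fits, among them limma-voom, which called 0 genes higher and 1 lower.

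The second comparison asked how LSK cells of R274X Tg mice differ from WT. Among genes of neutrophil granules, Elane, the neutrophil elastase, rose by 4.14 on the log2 scale (SE 0.71, adjusted p = 0.0130), from 119.0 ± 95.2 to 2095 ± 1508 CPM. It rose by 4.81 without WT replicate 4 and by 3.66 without Tg replicate 1. Prtn3, proteinase 3, rose by 2.86 (SE 0.46) and Ctsg, cathepsin G, by 2.85 (SE 0.49). Dntt, the terminal transferase of early lymphoid progenitors, fell by 1.70 on the log2 scale (SE 0.23, adjusted p = 0.00526) and Notch1, the receptor that starts T-lineage commitment, fell by 0.59 (SE 0.10). The mitotic genes Dlgap5 (-0.53, SE 0.077) and Nusap1 (-0.46, SE 0.071) fell by smaller amounts. In all, edgeR called 436 genes higher and 410 lower, of which 243 and 177 changed over 2-fold. Protein-coding genes made up 88.2% of the annotated calls and 77.0% of the annotated genes tested. The groups did not overlap for 746 of the 846 called genes, where 9.85% of the genes tested had such groups and chance gives 2.86%. Calls are selected on the same libraries for a difference large beside the spread, so the share among them is no separate support. The p-values measure the spread between libraries.

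Among genes without overlap that averaged at least 5 CPM over the 11 libraries, predicted models aside, the largest rises in Tg over WT were Wfdc21, Eno1b, Zfp990, Prom1, Fcnb, Mgam, Abca13, Cldn15, Elane and Sgms2. Eno1b, a copy of the enolase gene Eno1 whose reads the counting could share with it, rose by 5.90 (SE 0.24, adjusted p = 5.12e-07), from 0.292 ± 0.079 to 17.4 ± 2.18 CPM. Zfp990, a zinc finger gene in a cluster of close relatives, rose by 5.14 (SE 0.40), from 0.578 ± 0.316 to 20.3 ± 7.77 CPM. Prom1, which encodes the progenitor surface protein CD133, rose by 5.03 (SE 0.90), from 3.39 ± 3.18 to 106.1 ± 92.6 CPM. Fcnb, a ficolin of myeloid granules, rose by 4.86 (SE 1.07), Mgam, an intestinal-type maltase, by 4.84 (SE 0.80), Abca13 by 4.60 (SE 0.96), Cldn15, a claudin, by 4.38 (SE 0.71), Sgms2, a sphingomyelin synthase, by 4.09 (SE 0.76) and Wfdc21 by 6.84 (SE 1.24). The SD of Wfdc21 in Tg, 42.1 CPM, exceeded its mean of 34.8 CPM. Its log2 fold change was 5.49 without Tg replicate 1 and 9.03 without WT replicate 4, which held 26 of its WT counts. Without WT replicate 4 the log2 fold change was 5.80 for Prom1, 5.71 for Fcnb, 5.57 for Mgam, 5.39 for Abca13, 5.10 for Cldn15, 4.81 for Elane and 4.88 for Sgms2. It was 4.39 for Prom1, 4.04 for Abca13, 3.66 for Elane and 3.48 for Sgms2 without Tg replicate 1. Without Tg replicate 2 it was 4.12 for Fcnb, 3.99 for Mgam and 3.87 for Cldn15. The call of Abca13 was lost without any of 4 libraries (adjusted p up to 0.0745, without Tg replicate 1). So was that of Fcnb (up to 0.0845, without Tg replicate 2).

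The largest falls among such genes were Xist and 9 immunoglobulin segments, Igkv12-44, Ighv11-2, Igkv6-23, Igkv3-5, Igkv8-30, Iglv1, Ighv1-69, Iglc3 and Igkj2. Igkv12-44 had 0 counts in the 4 Tg libraries, at least 2010-fold lower than the pooled WT level of 42.1 CPM (against 3 counts over the Tg group) and at least 1190-fold without WT replicate 1. Iglv1 fell by 6.16 (SE 0.95), from 41.2 ± 38.9 to 0.570 ± 0.398 CPM. Of 158 immunoglobulin genes tested, 34 fell in Tg and 0 rose by edgeR. Immunoglobulin genes took 0.416 ± 0.423% of the counts in WT, 0.644 ± 0.518% in KO and 0.031 ± 0.007% in Tg. Within WT the share ran from 0.076% in replicate 3 to 1.03% in replicate 2. Whether these transcripts came from LSK cells or from other cells in the sorted fraction was not tested in any contrast. Jchain, of antibody-secreting cells, fell by 3.74 (SE 0.59) and Ighm by 3.30 (SE 0.77). Of the 11 libraries, leaving out 1 ended the call of Igkv3-5 for 9 (adjusted p up to 0.127, without Tg replicate 2), Ighm for 8 (0.102, Tg replicate 1), Igkj2 for 7 (0.122, Tg replicate 1) and Ighv1-69 for 6 (0.107, Tg replicate 1). Igkv8-30 lost it for 6 (0.0971, Tg replicate 2), Iglc3 for 5 (0.0950, Tg replicate 1), Igkv6-23 for 2 (0.0668, Tg replicate 1), Ighv11-2 for 2 (0.0770, Tg replicate 1) and Igkv12-44 for 1 (0.0527, Tg replicate 1). The log2 fold change of Igkv3-5 was -4.27 without WT replicate 4, and without WT replicate 2 that of Igkv6-23 was -5.35, that of Igkj2 -3.47, that of Jchain -3.08 and that of Ighm -2.37. All Tg counts of Igkv3-5 came from Tg replicate 1 and all of Igkv6-23 from Tg replicate 4.

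Of 20 granulocyte-monocyte progenitor genes 12 rose in Tg over all genes and 17 adjusted over the list alone (median 2.12; camera adjusted p = 2.87e-20; adjusted p = 0.339 with an estimated correlation). In Tg replicate 3 the list mean, 6.58 on the log2 CPM scale, lay near those of the KO libraries (6.36 to 6.57) and of WT replicate 4 (6.34), while the other Tg libraries held 7.32 to 8.19. Cst7 rose by 1.82 (SE 0.28) and Igsf6 by 3.01 (SE 0.51). Of 15 mature neutrophil genes 2 rose (Wfdc21 and Lcn2, 2.16, SE 0.52), and 5 higher and 1 lower passed adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.667 with an estimated correlation). Per library, S100a8 held 457.9, 224.4, 29.0 and 199.2 CPM of library totals in Tg, 28.5, 2.29, 2.83 and 39.97 in WT and 11.2, 23.1 and 29.1 in KO. Tg replicate 3 thus lay within the WT range. The call of the mature neutrophil list was lost without WT replicate 3 (camera adjusted p = 0.141). Lcn2 lost its call without any of 9 of the 11 libraries (adjusted p up to 0.113, without Tg replicate 2). Wfdc21 kept its call but lay between 5.49 without Tg replicate 1 and 9.03 without WT replicate 4.

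Of 18 lymphoid priming genes 7 fell and 12 did so adjusted over the list alone (camera adjusted p = 1.33e-10; adjusted p = 0.339 with an estimated correlation), among them Lsp1 (-0.80, SE 0.13) and Ikzf1 (-0.31, SE 0.071), which encodes the lymphoid regulator Ikaros. Of 18 B cell genes 2 fell (14 adjusted over the list alone; camera adjusted p = 6.4e-07; adjusted p = 0.515 with an estimated correlation), and 7 of 21 T and NK cell genes fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.000169; adjusted p = 0.515 with an estimated correlation), such as Ncr1 (-4.43, SE 0.69), Lck (-1.09, SE 0.18) and Nkg7 (1.36, SE 0.24). WT replicate 3 had the lowest WT means of these 3 lists on the log2 CPM scale. Its T and NK cell mean, -0.27, lay below every Tg library (-0.21 to 0.29), and its B cell mean, 0.53, within the Tg range (0.03 to 2.04). Its lymphoid priming mean, 5.23, lay below that of Tg replicate 4, 5.48. Of 17 macrophage genes 6 fell and 13 did so adjusted over the list alone (camera adjusted p = 1.23e-09; adjusted p = 0.445 with an estimated correlation), including Spic (-1.84, SE 0.28) and Cd5l (-4.42, SE 0.82) of tissue macrophages. Of 18 erythroid genes 2 fell, Hbb-bt (-1.81, SE 0.37) and Alas2 (-2.48, SE 0.56), and Tfrc rose (0.67, SE 0.17). In that list 9 lower and 1 higher passed adjusted over the list alone (camera adjusted p = 1.76e-06; adjusted p = 0.515 with an estimated correlation). Its mean in Tg replicate 4, 2.73 on the log2 CPM scale, lay above those in WT replicates 1 (2.49) and 3 (2.34). Among these genes, leaving out 1 of the 11 libraries ended the call of Ikzf1 for 9 (adjusted p up to 0.101, without Tg replicate 1), Tfrc for 9 (0.131, Tg replicate 1), and Alas2 for 8 (0.0871, WT replicate 2). Hbb-bt lost it for 2 (0.0627, Tg replicate 2) and Cd5l for 1 (0.0552, Tg replicate 1). The macrophage genes Mrc1 and Hmox1, also called lower, lost it for 8 (0.108, Tg replicate 1) and 4 (0.0736, Tg replicate 1). For the B cell, T and NK cell and macrophage lists, too, a source in other cells of the sorted fraction was not tested in any contrast.

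Of 52 genes of the G2 and M phases 13 fell and none rose over all genes, while 27 fell and 1 rose adjusted over the list alone (median -0.23; camera adjusted p = 1.71e-12; adjusted p = 0.445 with an estimated correlation). Of 42 S phase genes 3 fell, Clspn (-0.35, SE 0.062), Slbp (-0.34, SE 0.060) and Pcna (-0.28, SE 0.071), all 3 adjusted over the list alone too (camera adjusted p = 0.00484; adjusted p = 0.742 with an estimated correlation), and 1 of 32 replication-dependent histone genes fell, H1f1 (-0.62, SE 0.12), 2 adjusted over the list alone (camera adjusted p = 8.7e-05; adjusted p = 0.687 with an estimated correlation). Of 24 Polycomb genes Ezh2, the H3K27 methyltransferase, fell by 0.53 (SE 0.089), Cbx2 fell by 0.63 (SE 0.15) and Pcgf2 rose by 0.64 (SE 0.16), the same 3 adjusted over the list alone (camera adjusted p = 0.0308; adjusted p = 0.521 with an estimated correlation). Stem cell ageing genes were called higher, 1 over all genes (Gda, 3.43, SE 0.48) and 8 of 24 adjusted over the list alone (camera adjusted p = 3.39e-05; adjusted p = 0.515 with an estimated correlation). Of 20 glycolysis genes 2 rose, Aldoa (0.70, SE 0.13) and the lactate transporter Slc16a3 (0.83, SE 0.20), the same number adjusted over the list alone (camera adjusted p = 8.5e-05; adjusted p = 0.515 with an estimated correlation). Pcna lost its call whichever of the 11 libraries was left out (adjusted p up to 0.108, without Tg replicate 2). Pcgf2 lost it for 9 of them (0.110, Tg replicate 2), Slc16a3 for 9 (0.124, Tg replicate 2), and Cbx2 for 8 (0.110, Tg replicate 1). H1f1 (0.0550) and Aldoa (0.0546) lost it without Tg replicate 1. The S phase list was not called without WT replicate 3 (camera adjusted p = 0.276) or Tg replicate 4 (0.0611), nor the Polycomb list without WT replicate 1 (0.0579) or Tg replicate 1 (0.108).

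All 20 immediate early genes lay above WT (median 0.76; camera adjusted p = 2.92e-05; adjusted p = 0.660 with an estimated correlation), with 0 passing over all genes in edgeR, 9 adjusted over the list alone, 10 at an unadjusted p under 0.05 and 1 called by DESeq2. The list mean of WT replicate 4, 8.87 on the log2 CPM scale, lay above those of Tg replicates 1, 3 and 4 (8.48, 8.01 and 8.85). Tg replicate 2 held 9.58. Of 40 interferon response genes 1 fell, Ifi203 (-0.62, SE 0.12), also 1 adjusted over the list alone (median -0.32; camera adjusted p = 8.7e-05; adjusted p = 0.660 with an estimated correlation). The call of Ifi203 was lost for 3 of the 11 libraries left out (adjusted p up to 0.0654, without Tg replicate 1). Nuclear oxidative phosphorylation (53 of 60 above WT, median 0.16; camera adjusted p = 0.000334) and ribosome biogenesis (32 of 37, median 0.18; 0.000686) were called higher, with an adjusted p of 0.742 with an estimated correlation for both. In these lists 0 genes passed either way in edgeR, 8 and 9 had an unadjusted p under 0.05, and DESeq2 called 0 and 4. Leaving out 1 library moved these counts: edgeR called 125 higher and 86 lower without Tg replicate 1, 181 and 134 without Tg replicate 2, 151 and 149 without WT replicate 1, 158 and 134 without WT replicate 2, 281 and 273 without KO replicate 2, and 264 lower without WT replicate 4. Without the 4 libraries that held both Xist and Y-linked reads, which left 1 WT library assumed to vary like the others, edgeR called 9 higher and 11 lower.

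**Figure D3:**
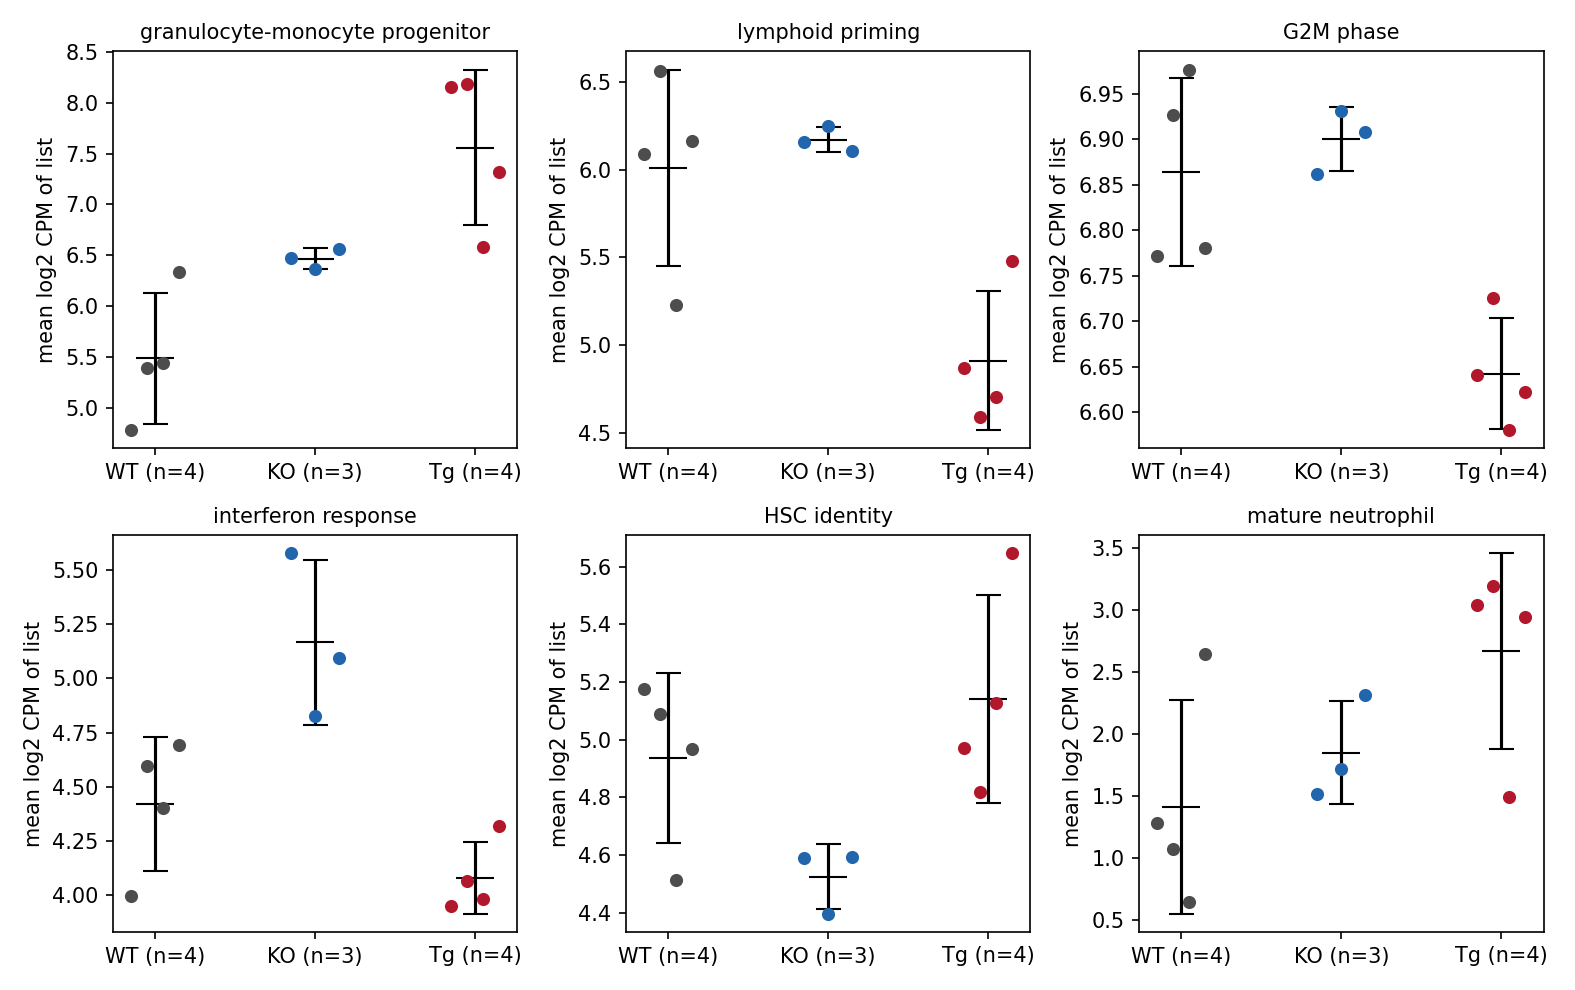
Mean log2 CPM of 6 gene lists per library (points), with mean and SD (bars), for WT (n = 4), KO (n = 3) and Tg (n = 4). Granulocyte-monocyte progenitor genes average 5.49 in WT, 6.47 in KO and 7.56 in Tg, and interferon response genes 4.42, 5.17 and 4.08.

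The third comparison tested Tg directly against KO. Interferon response genes fell in Tg against KO for 19 of 40 members over all genes and 32 adjusted over the list alone, with all 40 below KO (median -0.975; camera adjusted p = 4.1e-25; adjusted p = 0.261 with an estimated correlation). Irf7, the regulator of type I interferon genes, fell by 1.80 on the log2 scale (SE 0.27, adjusted p = 0.00463), and Xaf1 fell by 1.48 (SE 0.23), Rtp4 by 1.33 (SE 0.21) and Usp18 by 2.12 (SE 0.34). Of the stem cell genes, Esam, an endothelial-type adhesion molecule, rose by 1.13 (SE 0.19), Clec1a by 1.40 (SE 0.28) and Sult1a1 by 2.19 (SE 0.42). The calls of Clec1a (adjusted p = 0.0804) and Sult1a1 (0.0758) were lost without KO replicate 2. Leaving out 1 library ended them for 3 and 2 of the 11 libraries. Celsr1 rose by 1.36 (adjusted p = 3.35e-05) and Chl1 fell by 3.32 (adjusted p = 0.00128). In all, edgeR called 452 genes higher and 526 lower, of which 278 and 262 changed over 2-fold. The groups did not overlap for 98.9% of them, against 20.8% of the genes tested and 5.71% by chance. Here too the share among called genes follows largely from the calling.

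Stem cell identity genes rose for 5 of 26 members, 12 adjusted over the list alone (camera adjusted p = 4.47e-07; adjusted p = 0.476 with an estimated correlation), and stem cell ageing genes for 9 of 24, 16 adjusted over the list alone (camera adjusted p = 1.13e-10; adjusted p = 0.322 with an estimated correlation), such as Gstm2 (3.87, SE 0.56), Clu (3.20, SE 0.55) and the integrin Itga6 (0.59, SE 0.093). Clu lost its call without KO replicate 2 (adjusted p = 0.0517) and was at 2.57 without Tg replicate 4. Granulocyte-monocyte progenitor genes rose for 4 of 20, and 13 higher and 1 lower passed adjusted over the list alone (camera adjusted p = 3.49e-06; adjusted p = 0.476 with an estimated correlation). In that list the edgeR calls of Prtn3 (adjusted p = 0.144), Ctsg (0.154) and Cebpe (0.16) were lost without KO replicate 2. That of Nkg7 (0.0654) was lost without KO replicate 1. Lymphoid priming genes fell for 7 of 18, 11 adjusted over the list alone (camera adjusted p = 1.05e-11; adjusted p = 0.246 with an estimated correlation), and G2 and M phase genes for 14 of 52, 28 adjusted over the list alone (camera adjusted p = 6.5e-13; adjusted p = 0.376 with an estimated correlation). B cell genes fell for 5 of 18 (14 adjusted over the list alone), T and NK cell genes for 7 of 21 with 1 rising (7 and 2), macrophage genes for 3 of 17 (12), replication-dependent histone genes for 6 of 32 (11) and Ccr2 alone of 17 monocyte and dendritic cell genes (4), by 3.19 (SE 0.39). For these 5 lists, in that order, the camera adjusted p was 6.16e-11, 1.43e-05, 2.89e-06, 8.09e-07 and 8.09e-07 (adjusted p = 0.383, 0.383, 0.476, 0.476 and 0.476 with an estimated correlation). Without KO replicate 2 the edgeR calls of the macrophage genes Spic (adjusted p = 0.0521), Cd5l (0.101) and Cd163 (0.171) were lost. So were those of the histone genes H1f1 (0.0789), H4c3 (0.127) and H1f2 (0.134) and of Ighm (0.0684) in the B cell list. Without KO replicate 1 the calls of Cd22 (0.0712) and Cd79b (0.0874) in the B cell list and of the histone gene H2bc6 (0.159) were lost.

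Smaller groups also differed between Tg and KO. Of 14 NuRD genes, the remodelling and deacetylase complex, 3 fell, Mbd2 (-0.30), Hdac1 (-0.43) and Mta3 (-0.38), also 3 adjusted over the list alone (camera adjusted p = 0.0203; adjusted p = 0.476 with an estimated correlation). Itga2b, the platelet integrin, rose by 1.202 (SE 0.25) as 1 of 18 megakaryocyte genes, 3 adjusted over the list alone (0.0110; 0.476 with an estimated correlation), and Hoxb2 rose by 1.53 (SE 0.35) as 1 of 15 Hox genes, 2 adjusted over the list alone (0.0369; 0.530 with an estimated correlation). Hbb-bt fell by 1.68 (SE 0.39) as 1 of 18 erythroid genes, 1 adjusted over the list alone (4.84e-05, and 0.476 with an estimated correlation). Of 42 S phase genes 3 fell, Clspn, Slbp and Pcna, 5 adjusted over the list alone (0.000129, and 0.476 with an estimated correlation). Pfkfb3 rose by 0.29 (SE 0.076) as 1 of 20 glycolysis genes, with 1 higher and 1 lower adjusted over the list alone (0.00502, and 0.476 with an estimated correlation). Leaving out 1 of the 11 libraries ended the call of Pfkfb3 for 10 (adjusted p up to 0.198, without KO replicate 2), Pcna for 9 (0.160, KO replicate 2), and Mta3 for 8 (0.177, KO replicate 2). Hdac1 lost it for 7 (0.147, KO replicate 2), Mbd2 for 7 (0.157, KO replicate 1), Hoxb2 for 5 (0.133, KO replicate 2) and Hbb-bt for 5 (0.111, KO replicate 2). Slbp lost it for 4 (0.0985, KO replicate 1), Itga2b for 2 (0.0773, KO replicate 2) and Clspn for 1 (0.0505, KO replicate 2). Ribosomal protein genes (5 of 78 above KO, median -0.11; 0.00457) and class I antigen presentation (2 of 15, median -0.25; 0.0156) were called lower and immediate early genes (19 of 20, median 0.58; 0.0122) higher, with an adjusted p of 0.745, 0.476 and 0.724 in that order with an estimated correlation. In these last 3 lists edgeR passed 0 genes either way, 3, 5 and 4 members had an unadjusted p under 0.05, and DESeq2 called 1, 1 and 0. Without Tg replicate 4 the camera call was lost for NuRD (adjusted p = 0.0645), megakaryocyte (0.0539), Hox (0.103), ribosomal protein (0.280) and class I antigen presentation (0.0679) genes. It was also lost without KO replicate 1 (0.0999) or Tg replicate 3 (0.0690) for Hox, without KO replicate 2 for megakaryocyte (0.138), without KO replicate 3 for ribosomal protein (0.146) and without Tg replicate 2 for immediate early genes (0.268).

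Lists called by camera in none of the 3 contrasts were those of mast cells and basophils, stroma and endothelium, TNF and NF-kB response, heat shock, p53 targets, leukaemia self-renewal regulators, Notch pathway, cytokine STAT targets, TGF-beta and BMP response, mitochondrially encoded genes and cholesterol synthesis. Their lowest camera adjusted p was 0.0564, for mast cells and basophils in Tg against KO. Single members changed in Tg against WT, among them Stab2, a scavenger receptor of sinusoidal endothelium (-3.75, SE 0.61), Tie1 (0.49, SE 0.10), and Hdc, the histamine-forming enzyme (1.78, SE 0.36). In Tg against WT the stem cell identity list was not called (camera adjusted p = 0.0667), although Esam (0.73, SE 0.17) and Clec1a (1.04, SE 0.25) rose.

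By the same limits, the largest rises over KO were Eno1b (7.01, SE 0.30), Zfp990 (5.42, SE 0.46), Wfdc21, Abca13, Ncam1, Prom1, Mgam, Pcna-ps2, Phf6 (3.50, SE 0.20) and Chst13. Ncam1, the neural cell adhesion molecule, rose by 4.33 (SE 0.78), from 4.09 ± 1.44 to 81.6 ± 68.5 CPM, and by 3.57 without Tg replicate 1. Pcna-ps2 is a processed copy of Pcna. The largest falls were 9 immunoglobulin segments (Igkv1-133, Igkv12-44, Ighv1-58, Igkv8-21, Igkv3-12, Ighv11-2, Igkv9-120, Igkv14-126 and Igkv8-30) and Gbp2b, an interferon-induced guanylate-binding protein, which fell by 8.09 (SE 2.07), from 16.8 ± 12.8 to 0.061 ± 0.123 CPM. Igkv1-133, Igkv12-44, Ighv1-58 and Igkv8-21 had 0 counts in every Tg library, at least 1880-, 1600-, 1250- and 925-fold lower than in pooled KO. These limits fell to 164-fold for Igkv1-133 and 689-fold for Igkv12-44 without KO replicate 3. They fell to 978-fold for Ighv1-58 and 164-fold for Igkv8-21 without KO replicate 2. All 8 Tg counts of Gbp2b came from Tg replicate 4, and its log2 fold change was -7.25 without KO replicate 1. Gbp2b also had 0 counts in WT replicates 1 and 3, beside 28.14 and 10.35 CPM in WT replicates 2 and 4. Calls that ended when 1 of the 11 libraries was left out were those of Igkv8-21 for 9 (adjusted p up to 0.126, without KO replicate 2), Gbp2b for 8 (0.124, KO replicate 1), Ighv1-58 for 7 (0.0961, KO replicate 2), and Igkv1-133 for 5 (0.0776, Tg replicate 1). Others were Igkv3-12 for 5 (0.325, KO replicate 2, where its log2 fold change was -4.46), Ighv11-2 for 3 (0.0632, Tg replicate 1) and Igkv14-126 for 3 (0.0606, Tg replicate 1). Igkv8-30 kept its call, at -5.14 without KO replicate 2. Among the rises they were Wfdc21 for 5 (0.126), Abca13 for 5 (0.126), Prom1 for 5 (0.132), Mgam for 4 (0.104), Ncam1 for 2 (0.0553) and Pcna-ps2 for 2 (0.0670), each highest without KO replicate 2, and Chst13 for 3 (0.0775, KO replicate 1). Without KO replicate 1, 2 or 3 edgeR called 139, 109 and 150 genes higher and 216, 178 and 209 lower, and without Tg replicate 1 or 2 it called 212 and 243 higher and 191 and 258 lower. Without the libraries with both Xist and Y-linked reads it called 119 higher and 245 lower.

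No gene was called in the same direction in KO and Tg against WT by edgeR, where independent lists would share 0.0254 higher and 0.0716 lower. The few edgeR calls in KO keep that number near 0. DESeq2 called 15 in the same direction. The number that independent lists would share was not worked out for DESeq2, and WT libraries common to both contrasts can raise it. Across 13855 genes, which are not independent replicates, the log2 fold changes of the 2 genotypes had a Pearson r of 0.070. Unchanged groups simulated against the same WT libraries gave 0.46 (range 0.408 to 0.498). The covariance was 0.0176 against 0.0483 simulated, and with the WT libraries split 2 and 2 the r averaged -0.116 (range -0.291 to 0.0991).

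The libraries were also checked for sex-linked transcripts. Xist, expressed from the inactive X chromosome of female cells, held 50.02 to 53.8 CPM in WT and 32.7 to 40.3 in KO, and 0.031 to 0.297 in Tg. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y summed to 192.4, 49.9, 333.3 and 367.4 CPM in the Tg libraries. They summed to 132.6, 140.7, 0.064 and 20.96 CPM in the WT libraries and 114.2, 1.74 and 0.033 in the KO libraries, so that WT replicates 1, 2 and 4 and KO replicate 1 held both Xist and Y-linked reads. The difference between Tg and the other groups therefore coincides with the absence of Xist.

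**Figure D4:**
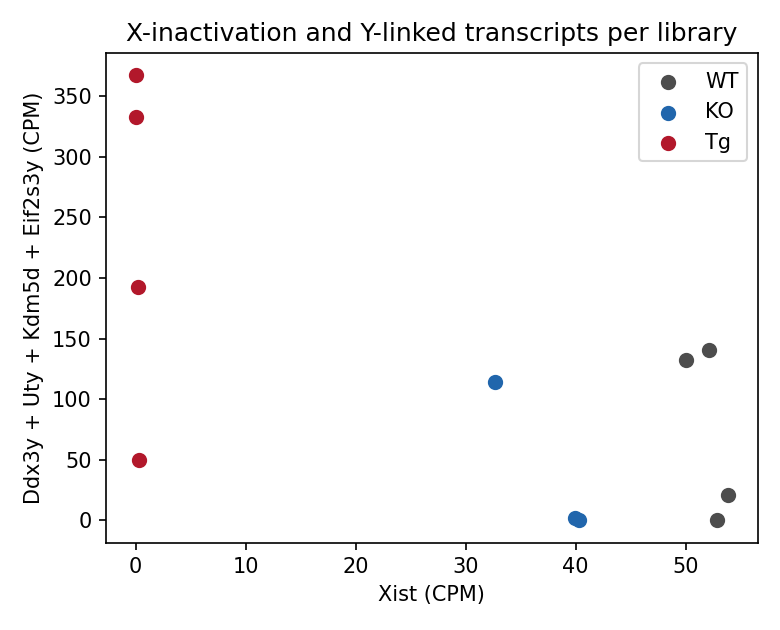
Xist (horizontal axis) against the summed Y-linked genes (vertical axis), both in CPM of library totals, 1 point per library. The 4 Tg libraries lie at 0.297 CPM of Xist or below, and 4 of the 7 WT and KO libraries hold 20.96 CPM or more of Y-linked reads beside Xist.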

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

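All tests of explanations given here, the counts of sample splits included, had their criteria written, and their genes chosen, after the results were seen. Among 152 groups of 4 libraries examined, 15 held a library far from the others. The cutoff would flag about 1 in 20 groups of independent, normally distributed values. Several of the flagged groups are of genes near 0 counts or of related immunoglobulin segments, so that rate does not apply to them. Igkv3-12 in Tg replicate 2 was flagged on 1 count.

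WT replicate 4 had the lowest total, 20990446 counts, against 30710000 to 31130000 in the other WT libraries. It also stood above the other WT libraries for Wfdc21 (1.246 CPM), Igkv3-5 (41.32 CPM), Chst13 (3.931 CPM) and Ighv1-58 (37.44 CPM). WT replicate 2 stood above them for Igkv6-23 (34.71 CPM), Igkj2 (36.4 CPM) and Igkv1-133 (14.88 CPM). Among the Tg libraries, replicate 1 stood apart for Chl1 (1.025 CPM) and Igkv3-5 (0.375 CPM), replicate 2 for Igkv3-12 (0.02697 CPM) and replicate 4 for Igkv6-23 (0.3995 CPM) and Gbp2b (0.2458 CPM). Within Tg, the mature neutrophil list was lowest in replicate 3 (mean log2 CPM 1.494) and the S phase list in replicate 4 (6.588).

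The changes from WT differed between KO and Tg in the direct test. The log2 difference, Tg minus KO, was 3.502 for Phf6, -3.32 for Chl1 and 1.363 for Celsr1. Its median was 1.34 over the stem cell ageing list, -2.73 over the B cell list and -0.975 over the interferon response list. With an estimated correlation none of these 3 lists was called (adjusted p = 0.322, 0.383 and 0.261).

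Granulocyte-monocyte progenitor genes were higher in Tg than WT. Mature neutrophils among the sorted cells were not decided by the test made. S100a8 plus S100a9 reached at most 0.0364 of Mpo plus Elane in a Tg library, where neutrophils alone would put it above 1. Mpo and Elane themselves rose in Tg, and WT replicate 1 held a ratio of 0.0383. A minority of neutrophils is therefore not excluded. Progenitors low in Sca-1 inside the sort gate, which selects Sca-1-positive cells, would lower the stem cell identity list. Its median log2 fold change was 0.136 (quartiles -0.0147 and 0.351), and Ly6a, which encodes Sca-1, held only 25.6 CPM in WT and 25.1 in Tg beside 729 and 768 CPM of Kit, for reasons not known, so this explanation stays open. The Tg genotype stays open as well, as a biological explanation that these tests leave undecided.

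Among called genes changed over 8-fold in Tg against both WT and KO, 46 were higher and 52 lower, the latter with 23 immunoglobulin genes and Xist, and 11, in either direction, had under 1 CPM in every library on the lower side and over 5 CPM in every library on the higher side. A strain or background difference may contribute: 18.6% of the 97 annotated genes were pseudogenes, against a median of 12.4% in expression-matched lists, of which 3.94% reached the observed share (24.7% of 73 without immunoglobulin genes and Xist, where 0.29% did). The labels give 1 strain for all mice and no batch. Reads split between near-identical copies by the counting could also affect this share, which was not tested. The pseudogene share therefore does not single out a background difference. A single segment around an inserted or targeted locus that holds most of these genes was argued against. The chromosome with most of them, chromosome 6, held 23, or 23.7% (95% Wilson interval 16.4 to 33.1%). Without immunoglobulin genes and Xist it held 13 of 73, or 17.8% (10.7 to 28.1%). A segment behind fewer of these genes was not tested. The genotype stays open.

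The sex of the mice could account for genes called between Tg and WT, since Xist was near 0 in Tg alone. Within WT and KO libraries, the called genes moved with the Y-linked level by a median of -0.185 of their Tg change (-0.271 to -0.135 leaving out 1 library). This cannot be told apart from the genotype, because the Y-linked reads of those libraries were not shown to come from male cells. Of the 35 splits of the 8 libraries, 1, the real one, gave 846 genes and the highest other gave 4. For Tg against KO 1 of 35 splits, the real one, gave 978 genes and the highest other 53. With 35 splits, 1 is the lowest count that can be reached. The other splits mix genotypes, which widens the spread and lowers their calls. These counts argue against chance in both contrasts but do not exclude it. For KO against WT 2 of 35 splits gave at least the 4 genes called, with 15 in the highest other, so chance was not excluded.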

How the results depend on the processing

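Fits chosen after the data were examined were those with the Y-linked level, without the libraries with both Xist and Y-linked reads, of autosomal protein-coding genes and with robust empirical Bayes. Counts are given as higher and lower, and the cause was not tested unless stated. Other scaling factors, the stricter filter, autosomal protein-coding genes and robust empirical Bayes kept every count within 1.5 times. Without a low-count filter 1 gene was shared by KO and Tg. Testing against 1.2-fold, a stricter null by construction, gave 1 lower in KO, 188 and 105 in Tg against WT (64.2% higher, against 51.5%) and 211 and 209 in Tg against KO. Fits of the groups compared alone gave 0 and 1 in KO and 194 and 164 in Tg against WT. A surrogate variable gave 0 and 1 in KO, 219 lower in Tg against WT and 329 lower in Tg against KO. limma-voom gave 0 and 1 in KO. DESeq2 gave 55 and 52, 914 and 930, and 942 and 932, with 15 shared. An estimated correlation called 0 lists higher and 0 lower in KO against WT, in Tg against WT and in Tg against KO. fry called 0 and 0, 1 and 2, and 1 and 4 lists. Its test for changes of mixed direction called 0, 22 and 26. The Y-linked level as a covariate gave 0 higher in KO, 786 and 636 in Tg against WT and 202 and 261 in Tg against KO. Without the libraries with both Xist and Y-linked reads, which leaves 1 WT library assumed to vary like the others, the values were 2 genes and 13 lists higher in KO, 9 and 11 genes in Tg against WT, 119 and 245 in Tg against KO, 3 shared, and 0.9363 for Phf6 in Tg against WT (adjusted p = 0.310). Leaving out 1 library gave 0 to 2 higher and 1 to 3 lower in KO with 3 to 8 lists lower (8 without WT replicate 3), 125 to 618 and 86 to 558 in Tg against WT, and 109 to 523 and 178 to 596 in Tg against KO. Phf6 in Tg against WT ranged from 0.7295 to 0.9411, and without WT replicate 2 its call was lost (0.8484, adjusted p = 0.0563). KO called 0 higher without WT replicate 2, 3 or 4 or KO replicate 2 or 3, 2 without KO replicate 1, and 1 lower without WT replicate 3 or 4, any KO replicate, or Tg replicate 1, 2 or 4. In Tg against WT the counts were 151 and 149 without WT replicate 1, 158 and 134 without WT replicate 2, 264 lower without WT replicate 4, 281 and 273 without KO replicate 2, 125 and 86 without Tg replicate 1, and 181 and 134 without Tg replicate 2. In Tg against KO they were 139 and 216, 109 and 178, and 150 and 209 without KO replicate 1, 2 and 3, 212 and 191 without Tg replicate 1, and 243 and 258 without Tg replicate 2. For single genes, 4975 values kept direction and side of the threshold, 749 lost the call, 150 gained it and 4, called under neither setting, changed sign, such as Ighm in KO against WT (-0.06122 without KO replicate 2). Depth limited values near 0: 3 counts were 0.0657 to 0.143 CPM.

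The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.245 to 0.0959, and 1 pair correlated best with its own number. With the number as a replicate block the counts were 0 and 1 in KO, 118 and 103 in Tg against WT and 124 and 179 in Tg against KO, and Phf6 in Tg against WT was 0.8571 (adjusted p = 0.0525).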

Other observations

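The tests of both hypotheses below were chosen after the results were seen, and so were the genes named. Meg3 and Rian, maternally expressed non-coding RNAs of an imprinted cluster, rose in Tg against WT by 3.6 (SE 0.45, adjusted p = 0.00324 by edgeR) and 4.16 (SE 0.37, adjusted p = 0.000233). Socs3, a feedback inhibitor of cytokine signalling, rose by 1.32 (SE 0.24) and Id1 by 2.48 (SE 0.45). Jag1, a Notch ligand, rose by 1.92 (SE 0.40) and Dtx4, a Notch pathway ubiquitin ligase, by 1.02 (SE 0.22), while Notch1 fell. Rab6b fell by 4.29 (SE 0.28) and Cmah, which makes a sialic acid, fell by 1.88 (SE 0.20).

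Celsr1 lay in the order KO, WT, Tg, as Phf6 did. A hypothesis is that expression of some genes may follow the Phf6 transcript level. Of 10374 autosomal genes, 67 had non-overlapping groups with WT in the middle, against 17 with KO in the middle and 1 with Tg in the middle (p = 3.5e-08 by a 2-sided exact binomial test across genes, which are not independent). Celsr1, which prompted the hypothesis, is itself counted among the 67. It was the only gene of these to pass in KO against WT (adjusted p = 0.0323 by edgeR). The others include Phf11d, Cdcp1 and Lama5 (adjusted p = 0.341, 0.372 and 0.294 by edgeR). The order does not separate the Phf6 level from other differences between the mice.

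Xist and Y-linked reads occurred in the same WT and KO libraries, although the labels describe RNA of individual mice. A hypothesis was that material of male and female mice met in a library. The male share was read from the highest Y-linked level in Tg, 367.4 CPM, while the other Tg libraries held 192.4, 49.9 and 333.3 CPM. A lower reference would raise the male share and lower the Xist left, so the values below depend on this choice. The 2 WT libraries with over 100 CPM of Y-linked reads averaged 51.1 CPM of Xist beside 52.8 in WT replicate 3, which lacked them, and lay 17.9 CPM above the 33.2 that the male share would have left. KO replicate 1 held 32.7 CPM, below the 39.9 and 40.3 of the KO libraries without such reads and 5.01 CPM above the 27.6 that the male share would have left. With 1 WT library without Y-linked reads and 1 KO library with over 100 CPM of them, a mixture cannot be told apart from another source of these reads.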
